A study of Homo sapiens with 12 samples.

How the data were processed

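RNA sequencing was done on 12 libraries of human astrocyte progenitors made from the H7 embryonic stem cell line, at day 160, sorted into 4 populations with 3 libraries each. Per the labels' protocols, RNA was extracted with a micro-scale column kit and libraries were made with a SMARTer mRNA kit. The processing notes name Trimmomatic 0.36, STAR 2.7.2a and featureCounts 1.5.3, and list a human build (hg38) and a mouse build. The gene coordinates in the files are human. The annotation release and whether reads were counted by strand are not stated.

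The deposited values come as 4 tables. A sheet gives the population and batch of each sample, and its batch numbers match the replicate numbers of all 12 titles. The deposited count table holds raw counts for 42492 genes, with totals from 11201161 to 45301112 per library, so that counting error is small beside the spread between libraries for all but weakly expressed genes. The deposited normalized table holds log2 values for 42484 genes. The last deposited table holds, for 6 pairs of populations, the log2 difference, the average log2 CPM, the p-value and the adjusted p-value. Among the lines of the last 2 tables, those of 8 genes are not analysed here.

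No label says how the log2 values were made. From the counts, edgeR 4.0.16 log2 CPM with TMM (trimmed mean of M-values) factors and a prior count of 2, followed by removal of batch means with limma 3.58.1, gave 509808 of 509808 log2 values within 1e-09 once the count columns were re-matched by value. Under the deposited headers 7.08% of the values were within that tolerance and the median difference was 0.343. The re-matched order is that of the sample numbers sorted as text (1, 10, 11, 12, 2 and so on). To choose between the headers, each library's deviation from its population mean was computed on unadjusted counts, since batch effects should be shared by libraries of 1 batch. In the order of the log2 table, deviations of the same batch number correlated across genes at 0.420 or more in all 18 pairs (mean 0.691). Under the headers of the count table the mean was 0.140 and the lowest -0.432. Genes are not independent replicates in these correlations. The headers of the log2 table were therefore used throughout, and batch was taken as a block.

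The reported fit is limma (R 4.3.3) with an intensity trend on the deposited log2 values, with a mean for each population and a term for batch, on the 16030 genes with a log2 value above 0 in at least 3 libraries. Because batch means had been removed from the values, leaving the batch term out would count 2 residual degrees of freedom too many. Contrasts were CD63-positive against negative averaged over CD71, CD71-positive against negative averaged over CD63, their interaction, the 6 pairs of populations, and a joint test of any difference. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. This departs from the design fixed before the data were examined, which was edgeR quasi-likelihood on the count table under its own headers with TMM and no batch term. The gene lists, the contrasts, the rule for naming genes and the first set of alternatives were fixed then as well.

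Named genes are the sort markers, the 8 largest differences in each direction among genes that passed with a mean log2 value of at least 2 and the same sign in both gates, up to 4 members with the smallest p of each list that was called or had at least 3 called members, and the 5 largest differences in each direction for each pair of populations. Where none passed, the 5 smallest p are given. Only part of these are written out. Errors of differences are standard errors from the fit, and pairs are libraries of the same batch. For CD63 and CD71 averaged, the 6 pairs come from only 3 batches, so they are not independent. The fit has no term for a CD63 or CD71 difference that varies between batches.

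Gene lists were written from general knowledge of cell types, pathways and published glioblastoma states, so their membership can differ from the published ones, and some genes stand in more than 1 list. The sort markers were left out of every list, so that the integrin, lysosome, iron, tetraspanin and housekeeping lists each lack 1 tested gene. The 49 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether a list moves on balance and does not compare it with other genes.

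Alternatives were DESeq2 1.42.0, limma voom, other scaling factors, filters and prior counts, re-matched counts with and without batch, thinning to the smallest total, and leaving out each library. Splits of the samples were drawn with batches kept together where all 12 libraries are used. The fit was tested on simulated data in which 100 genes changed by 1 and 100 others by 2 on the log2 scale. All had a mean log2 value of at least 2, so recovery of weaker genes was not tested. Simulated genes varied independently of each other, which real genes need not do, so the rates can overstate what the fit detects. In the data ANLN at 1.25 ± 0.23 and GAD1 at -1.30 ± 0.20 did not pass for CD71. Nor did MYO5B at -1.96 ± 0.29 for the interaction. It recovered 69% of changes of 1 and 99% of changes of 2 on the log2 scale for CD63, 74% of changes of 1 and 98% of changes of 2 on the log2 scale for CD71, 18% of changes of 1 and 95% of changes of 2 on the log2 scale for CD63 in CD71-negative cells and 2% of changes of 1 and 61% of changes of 2 on the log2 scale for the interaction. No 2 libraries of a population were duplicates. Sort gates, surface protein levels and purity are not in the files.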

Results

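The series holds 12 RNA sequencing libraries from astrocyte progenitors that were derived from H7, an established human embryonic stem cell line, and collected at day 160 of differentiation. All of the cells carried CD51, the surface integrin encoded by ITGAV. They were sorted into 4 populations by CD71, the transferrin receptor encoded by TFRC, and by CD63, a tetraspanin of late endosomes and extracellular vesicles. The populations are called double-negative, CD63-only, CD71-only and double-positive here, and each has 3 libraries that the deposited sheet assigns to batches 1, 2 and 3. The labels do not say whether the batches were separate differentiations. Total counts ranged from 11201161 to 45301112 per library. Their means were 18432028 ± 3183047 (SD, n = 3) in double-negative, 18788539 ± 2663291 in CD63-only, 13600032 ± 2256942 in CD71-only and 32112171 ± 11509347 in double-positive libraries. Mitochondrially encoded transcripts took 1.08% ± 0.328 (SD, n = 3) of the counts in double-negative, 1.29% ± 0.437 in CD63-only, 2.07% ± 0.877 in CD71-only and 1.35% ± 0.328 in double-positive libraries.

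The headers of the deposited count table and of the deposited log2 table name the same columns differently, with only 1 of 12 columns given the same library. The comparisons rest on the log2 table under its own headers, a choice made after both tables were seen. Library names in the text are those of the log2 table, and counts are re-matched to it by value. The edgeR fit first planned takes the count table under its own headers and called 0 genes in all 10 comparisons, against between 129 and 1336 genes at an unadjusted p under 0.05. DESeq2 under the same headers called between 1 and 11 genes in 6 comparisons and 0 in the other 4, and limma voom called 0 in all 10. Of 126 values of named genes, 67 had the opposite sign in the edgeR fit first planned. Many directions given for the populations therefore depend on which headers are right. Batch deviations and CD63 RNA argue against the headers of the count table. In the order of the log2 table, 12 of 12 libraries correlated best with a library of their own batch, against 5 under the count headers. All 6 CD63-positive libraries lay above every CD63-negative one in CD63 RNA, against 0 under the count headers.

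The first question was whether the RNA of the sort markers followed the gates. CD63 RNA (ENSG00000135404.11, chromosome 12, 55725323 to 55729707, hg38) was higher in the CD63-positive populations by 0.88 ± 0.11 (log2, standard error, n = 6 libraries against 6), in 6 of 6 same-batch pairs (limma, Benjamini-Hochberg adjusted p = 0.00289). Its log2 normalized expression was 8.18 ± 0.092 (SD, n = 3) in double-negative, 9.06 ± 0.089 in CD63-only, 8.02 ± 0.28 in CD71-only and 8.90 ± 0.14 in double-positive libraries. Each of the 6 CD63-positive libraries lay above all CD63-negative ones. TFRC (ENSG00000072274.13, chromosome 3, 196027183 to 196082096) was 0.71 ± 0.20 higher in the CD71-positive populations in 6 of 6 pairs without passing (limma, Benjamini-Hochberg adjusted p = 0.0775, or 0.0400 without double-negative replicate 2). With another library left out its limma adjusted p rose to as much as 0.189. Its means were 7.21 ± 0.42, 7.61 ± 0.35, 7.93 ± 0.34 and 8.29 ± 0.25 in the same order. ITGAV (ENSG00000138448.12, chromosome 2, 186590056 to 186680901), which all populations were gated on, was also higher with CD63 by 0.78 ± 0.10 (limma, Benjamini-Hochberg adjusted p = 0.00344) and differed by -0.0049 ± 0.10 with CD71. CD63 RNA differed by -0.16 ± 0.11 with CD71 and TFRC by 0.38 ± 0.20 with CD63, neither passing (limma, Benjamini-Hochberg adjusted p = 0.397 and 0.194). The interaction estimates were 0.30 ± 0.20 for ITGAV, 0.0063 ± 0.22 for CD63 and -0.042 ± 0.39 for TFRC, and none passed. Under the headers of the count table no CD63-positive library lies above all CD63-negative ones, and the mean log2 CPM of CD63 differs by -0.24 with CD63.

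**Figure D1:**
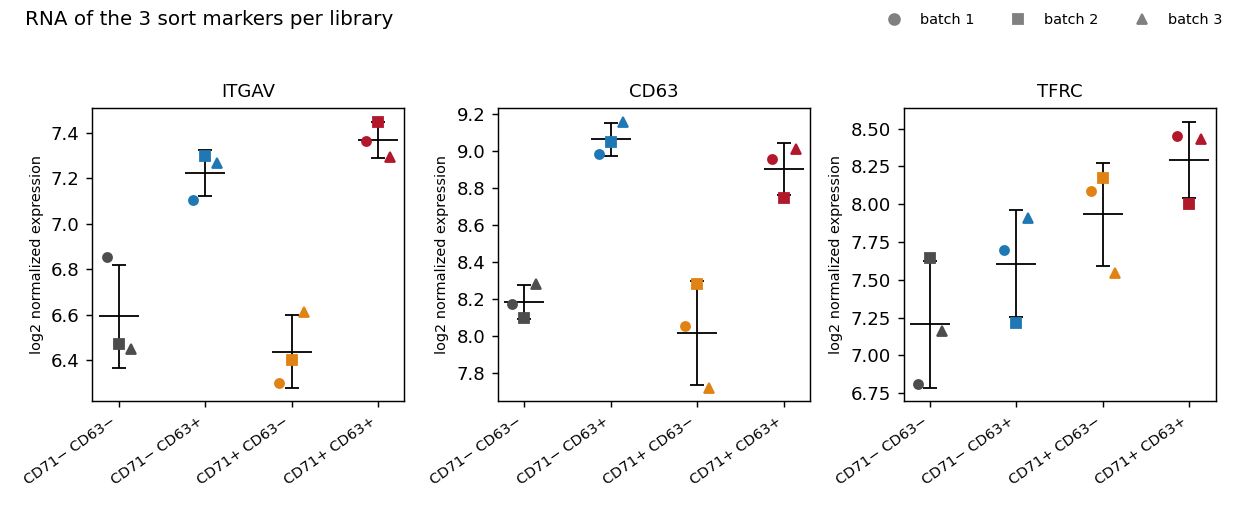
Log2 normalized expression (vertical axis, log2 CPM) of ITGAV, CD63 and TFRC in the 12 libraries by population (horizontal axis). Points are libraries with 1 symbol per batch, and bars are the mean and SD of 3 libraries. CD63 means are 9.06 and 8.90 in the CD63-positive populations and 8.18 and 8.02 in the others.

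The next question was how cells sorted as CD63-positive differed from CD63-negative ones, averaged over CD71 (6 libraries against 6). Many genes of neurons were lower in the CD63-positive populations. Doublecortin (DCX, ENSG00000077279.18, chromosome X, 111293779 to 111412429), a microtubule protein of migrating young neurons, differed by -1.74 ± 0.13 on the log2 scale, GAD1, which makes GABA, by -1.83 ± 0.20, and STMN2, a growth cone protein, by -3.27 ± 0.43. Each had this sign in 6 of 6 pairs (limma, Benjamini-Hochberg adjusted p = 0.000861, 0.00226 and 0.00355). The calcium-binding proteins SCGN (ENSG00000079689.14, chromosome 6, 25652201 to 25701783) at -3.83 ± 0.54 and CALB2 at -3.02 ± 0.44 were among the largest differences in this direction, together with KLHL35 at -3.36 ± 0.66 in 5 of 6 pairs. The neuronal chromatin remodelling subunit ACTL6B differed by -2.97 ± 0.34, the forebrain interneuron transcription factor DLX5 by -2.48 ± 0.44 and the transcription factor ST18 by -2.41 ± 0.34. DLX6-AS1, at -2.59 ± 0.54, overlaps genes on the other strand, and the labels do not state stranded counting, so its reads cannot be told from theirs.

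The sort markers were left out of all lists. In the neuron list, 1 of 19 tested members were higher, 13 lower and 5 did not pass (2 higher and 16 lower when adjusted over the list alone). The neuron list had a median log2 difference of -1.53, camera adjusted p = 1.04e-09 and adjusted p = 0.149 with an estimated correlation. The member that was higher was the neurofilament gene NEFL, at 1.65 ± 0.37, chosen after its values were seen. Its adjusted p was 0.0572 without CD71-only replicate 3. Among genes listed for the NPC-like states of glioblastoma (GBM), which resemble neural progenitors, in state 2, 0 of 48 tested members were higher, 31 lower and 17 did not pass (0 higher and 32 lower when adjusted over the list alone). NPC-like state 2 had a median log2 difference of -0.63, camera adjusted p = 1.41e-18 and adjusted p = 0.149 with an estimated correlation. In NPC-like state 1, 1 of 49 tested members were higher, 17 lower and 31 did not pass (2 higher and 21 lower when adjusted over the list alone). NPC-like state 1 had a median log2 difference of -0.41, camera adjusted p = 1.97e-08 and adjusted p = 0.149 with an estimated correlation. Its members SOX11, a neuronal progenitor transcription factor, and the neuronal tubulin TUBB3 differed by -1.30 ± 0.13 and -0.81 ± 0.11. In the bulk proneural list, 2 of 26 tested members were higher, 10 lower and 14 did not pass (3 higher and 10 lower when adjusted over the list alone). The proneural list had a median log2 difference of -0.32, camera adjusted p = 0.000314 and adjusted p = 0.185 with an estimated correlation. Among forebrain regional genes, 0 of 16 tested members were higher, 4 lower and 12 did not pass (0 higher and 6 lower when adjusted over the list alone). The regional list had a median log2 difference of -0.50, camera adjusted p = 0.0105 and adjusted p = 0.440 with an estimated correlation.

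A part of the genes listed for astrocytes and radial glia was higher with CD63. The acyl-CoA synthetase ACSBG1 rose by 2.10 ± 0.26, the lipid carrier APOE by 2.53 ± 0.42, CD44 by 1.61 ± 0.26 and clusterin (CLU) by 1.35 ± 0.22, while the transcription factor NFIB fell by 0.64 ± 0.10. In the astrocyte identity list, 12 of 27 tested members were higher, 1 lower and 14 did not pass (15 higher and 3 lower when adjusted over the list alone). The astrocyte identity list had a median log2 difference of 1.15, camera adjusted p = 0.000587 and adjusted p = 0.327 with an estimated correlation. The intermediate filaments vimentin (VIM) and nestin (NES) were higher by 1.63 ± 0.20 and 1.41 ± 0.13 and the radial glial fatty acid binding protein FABP7 by 1.33 ± 0.14. In the radial glia list, 9 of 20 tested members were higher, 0 lower and 11 did not pass (9 higher and 0 lower when adjusted over the list alone). The radial glia list had a median log2 difference of 0.74, camera adjusted p = 0.000587 and adjusted p = 0.246 with an estimated correlation. In the reactive astrocyte list, 14 of 19 tested members were higher, 0 lower and 5 did not pass (15 higher and 0 lower when adjusted over the list alone). The reactive astrocyte list had a median log2 difference of 1.15, camera adjusted p = 2.84e-06 and adjusted p = 0.149 with an estimated correlation. For the glioblastoma astrocyte-like state, 26 of 38 tested members were higher, 0 lower and 12 did not pass (32 higher and 0 lower when adjusted over the list alone). The astrocyte-like list had a median log2 difference of 1.18, camera adjusted p = 2.68e-11 and adjusted p = 0.245 with an estimated correlation.

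Matrix, adhesion and contractile genes were among those higher with CD63 as well. SPARC (ENSG00000113140.11, chromosome 5, 151661096 to 151686975), a secreted matrix protein, was higher by 1.94 ± 0.14 (limma, Benjamini-Hochberg adjusted p = 0.000861), laminin LAMA4 by 2.15 ± 0.33 and fibrillin FBN1 by 1.68 ± 0.17. In the matrix list, 19 of 29 tested members were higher, 0 lower and 10 did not pass (23 higher and 0 lower when adjusted over the list alone). The matrix list had a median log2 difference of 1.13, camera adjusted p = 1.97e-08 and adjusted p = 0.149 with an estimated correlation. Of the integrins, ITGB4 rose by 2.36 ± 0.51, ITGB3 by 1.97 ± 0.31 and ITGA3 by 1.45 ± 0.20. ITGB3 was weakly expressed, near the filter. Its log2 means were -2.11 in double-negative, -0.52 in CD63-only, -1.88 in CD71-only and 0.47 in double-positive libraries. In the integrin list, 10 of 12 tested members were higher, 0 lower and 2 did not pass (10 higher and 0 lower when adjusted over the list alone). The integrin list had a median log2 difference of 0.97, camera adjusted p = 1.72e-05 and adjusted p = 0.149 with an estimated correlation. Smooth muscle actin (ACTA2) and transgelin (TAGLN), proteins of contractile cells, were higher by 2.63 ± 0.23 and 2.06 ± 0.22. In the mesenchymal and mural list, 5 of 13 tested members were higher, 0 lower and 8 did not pass (5 higher and 0 lower when adjusted over the list alone). The mesenchymal and mural list had a median log2 difference of 1.44, camera adjusted p = 0.00472 and adjusted p = 0.228 with an estimated correlation. The glioblastoma mesenchymal-like state 1 list holds EMP1, at 2.77 ± 0.30, and gelsolin (GSN), at 1.72 ± 0.17. EMP1 was weakly expressed, with log2 means of -1.09 in double-negative, 1.91 in CD63-only, 0.50 in CD71-only and 3.04 in double-positive libraries. In this list, 34 of 44 tested members were higher, 0 lower and 10 did not pass (36 higher and 0 lower when adjusted over the list alone). Mesenchymal-like state 1 had a median log2 difference of 1.06, camera adjusted p = 2.85e-15 and adjusted p = 0.149 with an estimated correlation. In mesenchymal-like state 2, 15 of 46 tested members were higher, 2 lower and 29 did not pass (17 higher and 2 lower when adjusted over the list alone). Mesenchymal-like state 2 had a median log2 difference of 0.38, camera adjusted p = 0.00195 and adjusted p = 0.454 with an estimated correlation. In the bulk mesenchymal list, 12 of 24 tested members were higher, 1 lower and 11 did not pass (15 higher and 1 lower when adjusted over the list alone). The bulk mesenchymal list had a median log2 difference of 0.96, camera adjusted p = 4.32e-05 and adjusted p = 0.228 with an estimated correlation.

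The membrane repair protein MYOF (ENSG00000138119.17, chromosome 10, 93306429 to 93482334) had among the largest differences, at 2.77 ± 0.25 (limma, Benjamini-Hochberg adjusted p = 0.00162). The antigen-presentation genes CD74 and HLA-DRA were higher by 2.66 ± 0.55 and 2.35 ± 0.49, the retinoid isomerase RPE65 by 2.56 ± 0.47 and osteopontin (SPP1) by 2.29 ± 0.34. In the antigen presentation list, 8 of 15 tested members were higher, 0 lower and 7 did not pass (13 higher and 0 lower when adjusted over the list alone). The antigen presentation list had a median log2 difference of 0.61, camera adjusted p = 5.72e-05 and adjusted p = 0.267 with an estimated correlation. Lysosomal genes that were higher include the protease CTSB, by 0.72 ± 0.077, and the sterol carrier NPC2, by 0.86 ± 0.13. In the lysosome list, 16 of 26 tested members were higher, 0 lower and 10 did not pass (16 higher and 0 lower when adjusted over the list alone). The lysosome list had a median log2 difference of 0.49, camera adjusted p = 3.86e-05 and adjusted p = 0.228 with an estimated correlation. Of the iron genes, the ferrireductase STEAP3 rose by 1.38 ± 0.15. In the iron list, 8 of 15 tested members were higher, 0 lower and 7 did not pass (11 higher and 0 lower when adjusted over the list alone). The iron list had a median log2 difference of 0.59, camera adjusted p = 0.00115 and adjusted p = 0.245 with an estimated correlation. In cholesterol biosynthesis, 14 of 24 tested members were higher, 0 lower and 10 did not pass (18 higher and 0 lower when adjusted over the list alone). The cholesterol list had a median log2 difference of 0.47, camera adjusted p = 1.13e-06 and adjusted p = 0.267 with an estimated correlation. The mitotic kinesin KIF20A was higher by 1.18 ± 0.26. In the mitosis list, 13 of 33 tested members were higher, 0 lower and 20 did not pass (30 higher and 0 lower when adjusted over the list alone). The mitosis list had a median log2 difference of 0.93, camera adjusted p = 3.04e-07 and adjusted p = 0.454 with an estimated correlation.

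In the housekeeping list, 3 of 14 tested members were higher, 0 lower and 11 did not pass (5 higher and 0 lower when adjusted over the list alone). The housekeeping list had a median log2 difference of 0.28, camera adjusted p = 0.0132 and adjusted p = 0.430 with an estimated correlation. That median was 0.24 with RLE (DESeq2-type) factors and 0.14 with library sizes only. In total 3074 of 16030 genes passed for CD63, 2154 higher and 920 lower (limma on log2 values with batch as a term, Benjamini-Hochberg adjusted p under 0.05). Of 49 lists, camera with its preset correlation called 28 higher and 6 lower and fry called 36. With an estimated correlation 0 passed (smallest adjusted p = 0.149). EdgeR on the re-matched counts called 2457 genes with batch as a term, 1316 higher and 1141 lower (1012 and 1398 when scaled by library totals). It called 147 without batch, and 0 under the headers of the count table. With libraries left out the limma count fell to 1879 without CD63-only replicate 1, 1621 without CD63-only replicate 3 and 1389 without CD71-only replicate 3. It was 2029 without double-positive replicate 2 and 1780 without double-positive replicate 3.

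**Figure D2:**
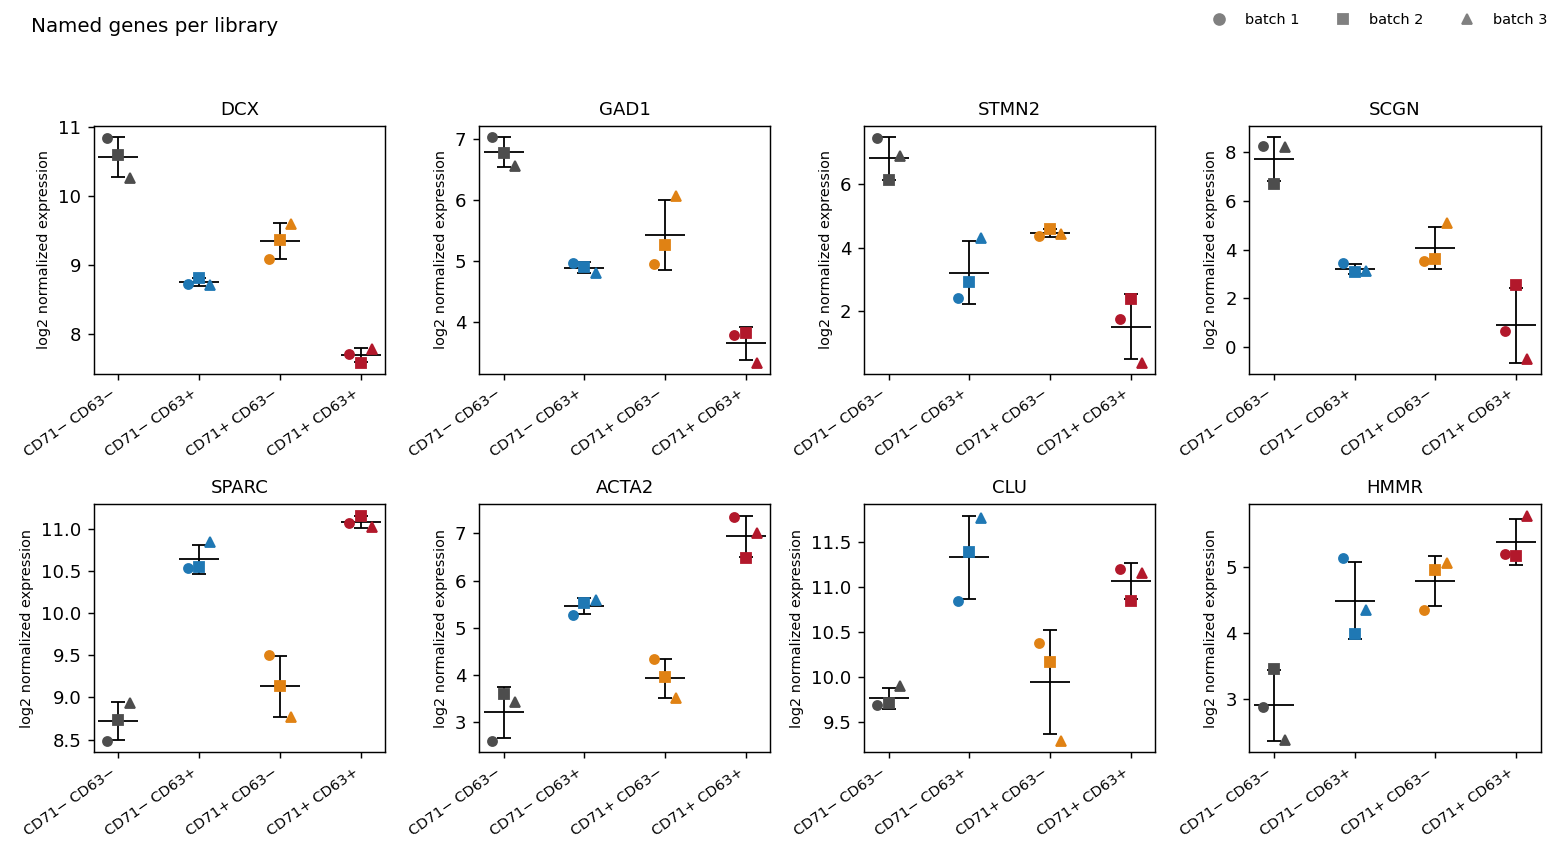
Log2 normalized expression (vertical axes, log2 CPM) of 8 named genes in the 12 libraries by population (horizontal axes). Points are libraries with 1 symbol per batch, and bars are the mean and SD of 3 libraries. DCX runs from 10.57 in double-negative to 7.69 in double-positive libraries, and SPARC from 8.72 to 11.09.

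The same question was asked within each CD71 gate (3 libraries against 3). Among CD71-negative cells, RPE65 was higher with CD63 by 3.19 ± 0.67, the signalling regulator RGS6 by 2.999 ± 0.63, LAMA4 by 2.82 ± 0.47, the long noncoding RNA MIR4435-2HG by 2.71 ± 0.57 and the adenosine receptor ADORA2B by 2.68 ± 0.60. In the same cells KLHL35, SCGN, CALB2, STMN2 and ACTL6B differed by -4.98 ± 0.94, -4.50 ± 0.77, -3.91 ± 0.62, -3.59 ± 0.61 and -3.27 ± 0.48. Among CD71-positive cells, ACTA2 was higher by 3.01 ± 0.33, MYOF by 2.99 ± 0.35, APOE by 2.95 ± 0.59, TAGLN by 2.58 ± 0.31 and the matricellular gene CCN2 by 2.54 ± 0.46. There STMN2, ACTL6B, ST18, LINC00599 and the neuronal transcription factor MYT1 differed by -2.95 ± 0.61, -2.66 ± 0.48, -2.54 ± 0.48, -2.49 ± 0.54 and -2.32 ± 0.44. All 20 of these differences had the same sign in 3 of 3 pairs, with adjusted p from 0.0164 to 0.0446 (limma, Benjamini-Hochberg). The gates shared 205 of the genes called higher, where independent lists of 580 and 505 would share 18.3. They shared 37 of those called lower, where lists of 253 and 129 would share 2.04. The lists are not independent, since both gates use 1 fit with a common spread for each gene, and genes are correlated. The excess therefore does not measure how far the gates agree.

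In all 833 genes passed among CD71-negative cells (580 higher, 253 lower) and 634 among CD71-positive cells (505 higher, 129 lower), by limma with all 12 libraries and batch as a term. EdgeR on re-matched counts called 401 and 36 with batch and 0 and 0 without it. Limma on the 6 libraries alone called 0 and 199, and thinning the counts to the smallest total left 217 among CD71-positive cells. Leaving out libraries took the first count to 10 without double-negative replicate 1 and 288 without double-negative replicate 3. It was 0 without CD63-only replicate 1, 509 without CD63-only replicate 2 and 0 without CD63-only replicate 3. It was 413 without double-positive replicate 1 and 439 without double-positive replicate 2. The second count went to 28 without double-negative replicate 2 and 136 without double-negative replicate 3. It was 124 without CD63-only replicate 1, 180 without CD63-only replicate 2 and 40 without CD63-only replicate 3. It was 86 without CD71-only replicate 1, 0 without CD71-only replicate 2 and 0 without CD71-only replicate 3. It was 416 without double-positive replicate 1, 0 without double-positive replicate 2 and 1 without double-positive replicate 3. Each of the 20 named differences kept its sign in every such fit and lost its call in 3 to 11 of the 12.

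Averaged over CD63, cells sorted as CD71-positive had lower levels of a few neuronal genes than CD71-negative cells (6 libraries against 6). The neuronal stathmin STMN4 differed by -1.26 ± 0.15 on the log2 scale, the microtubule proteins tau (MAPT), DCX and TUBB3 by -1.16 ± 0.13, -1.14 ± 0.13 and -0.90 ± 0.11. Synaptophysin (SYP), a synaptic vesicle protein, differed by -0.81 ± 0.10. The glycerol phosphate dehydrogenase GPD1 (ENSG00000167588.13, chromosome 12, 50103982 to 50111313) at -1.98 ± 0.25, CYTH1 at -0.75 ± 0.090 and the zinc finger gene ZNF821 at -0.65 ± 0.081 were also lower, as was ZNF71 at -0.57 ± 0.073, which was chosen after its values were seen. Fibrillin FBN1 (ENSG00000166147.13, chromosome 15, 48408306 to 48645849) was the only gene called higher, by 1.39 ± 0.17. Each of the 10 genes had the same sign in 6 of 6 pairs, with adjusted p from 0.0378 to 0.0414 (limma, Benjamini-Hochberg).

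Several lists were called for CD71 by camera with its preset correlation, although few of their members passed and none of the lists did with an estimated correlation. In the mitosis list, 0 of 33 tested members were higher, 0 lower and 33 did not pass (32 higher and 0 lower when adjusted over the list alone). The mitosis list had a median log2 difference of 1.14, camera adjusted p = 5.01e-18 and adjusted p = 0.393 with an estimated correlation. Its members ANLN and HMMR had values of 1.25 ± 0.23 and 1.38 ± 0.27 (adjusted p = 0.0524 and 0.0548, limma, Benjamini-Hochberg). Among DNA replication genes, 0 of 30 tested members were higher, 0 lower and 30 did not pass (10 higher and 0 lower when adjusted over the list alone). The replication list had a median log2 difference of 0.51, camera adjusted p = 1.50e-08 and adjusted p = 0.490 with an estimated correlation. In the neuron list, 0 of 19 tested members were higher, 2 lower and 17 did not pass (1 higher and 12 lower when adjusted over the list alone). The neuron list had a median log2 difference of -0.97, camera adjusted p = 1.14e-06 and adjusted p = 0.258 with an estimated correlation. GAD1 had a value of -1.30 ± 0.20 without passing (limma, Benjamini-Hochberg adjusted p = 0.0516, or 0.0345 without double-negative replicate 2, 0.0430 without CD71-only replicate 2 and 0.0150 without CD71-only replicate 3). Leaving out other libraries raised its limma adjusted p to as much as 0.139. For GBM NPC-like state 2, 0 of 48 tested members were higher, 3 lower and 45 did not pass (0 higher and 33 lower when adjusted over the list alone). NPC-like state 2 had a median log2 difference of -0.56, camera adjusted p = 5.90e-19 and adjusted p = 0.258 with an estimated correlation. For NPC-like state 1, 0 of 49 tested members were higher, 2 lower and 47 did not pass (1 higher and 17 lower when adjusted over the list alone). NPC-like state 1 had a median log2 difference of -0.43, camera adjusted p = 6.40e-09 and adjusted p = 0.258 with an estimated correlation. SOX11 had a value of -0.90 ± 0.13 (limma, Benjamini-Hochberg adjusted p = 0.0516, or 0.0309 without double-negative replicate 2 and 0.0430 without CD71-only replicate 2). Its limma adjusted p also reached 0.139 with another library left out. Among matrix genes, 1 of 29 tested members were higher, 0 lower and 28 did not pass (11 higher and 0 lower when adjusted over the list alone). The matrix list had a median log2 difference of 0.56, camera adjusted p = 4.19e-08 and adjusted p = 0.258 with an estimated correlation. The collagen COL1A1 and nidogen NID1 had values of 2.69 ± 0.48 and 1.72 ± 0.36 without passing (that of NID1 at 0.0567, or 0.0334 without double-negative replicate 2 and 0.0467 without CD71-only replicate 2). With other libraries left out the limma adjusted p reached 0.139 for COL1A1 and 0.153 for NID1. COL1A1 was weakly expressed, with log2 means of -0.40 ± 0.32 (SD, n = 3) in double-negative and 1.29 ± 1.23 in CD63-only libraries. For the GBM mesenchymal-like state 1, 0 of 44 tested members were higher, 0 lower and 44 did not pass (5 higher and 1 lower when adjusted over the list alone). Mesenchymal-like state 1 had a median log2 difference of 0.33, camera adjusted p = 2.47e-05 and adjusted p = 0.258 with an estimated correlation. In the mitochondrially encoded list, 0 of 13 tested members were higher, 0 lower and 13 did not pass (10 higher and 0 lower when adjusted over the list alone). The mitochondrial list had a median log2 difference of 0.58, camera adjusted p = 2.26e-06 and adjusted p = 0.465 with an estimated correlation. That median was 0.57 with RLE factors and 0.63 with library sizes only. With each gene centred on its mean over the 12 libraries, the list averaged -0.31 in double-negative and -0.21 in CD63-only libraries. It averaged 0.56 in CD71-only and -0.036 in double-positive ones. The rise thus lay mostly in CD71-only libraries, which also had the lowest mean total counts. MT-CO1, a subunit of the respiratory chain, had a value of 0.77 ± 0.19 in 4 of 6 pairs (limma, Benjamini-Hochberg adjusted p = 0.0655). Of the iron genes, which serve the pathway of the sort marker, 0 of 15 tested members were higher, 0 lower and 15 did not pass (0 higher and 0 lower when adjusted over the list alone). The iron list had a median log2 difference of 0.022, camera adjusted p = 0.864 and adjusted p = 0.970 with an estimated correlation.

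In all 10 genes passed for CD71, 1 higher and 9 lower, against 3893 at an unadjusted p under 0.05 (limma with batch as a term). With a looser limit of 0.10 on the limma adjusted p, 1780 genes passed for CD71 and 4875 for CD63. The count of 10 thus depends strongly on the threshold. Of 49 lists camera called 17 higher and 6 lower and fry 10, and 0 passed with an estimated correlation (smallest adjusted p = 0.258). On re-matched counts with batch, edgeR called 16 genes (7 higher, 9 lower), limma voom 194 genes (68 higher, 126 lower) and DESeq2 1835 genes (880 higher, 955 lower). With library sizes only edgeR called 14 genes (7 higher, 7 lower). EdgeR without batch called 0, and limma with a stricter expression filter called 70 genes (11 higher, 59 lower). Without a filter limma called 1 gene higher and 4 lower, and after thinning to the smallest total it called 0. Leaving out libraries took the limma count to 0 without double-negative replicate 1, 866 without double-negative replicate 2 and 1 without double-negative replicate 3. It was 0 without CD63-only replicate 1, 0 without CD63-only replicate 2 and 0 without CD63-only replicate 3. It was 0 without CD71-only replicate 1, 423 without CD71-only replicate 2 and 1 without CD71-only replicate 3. It was 1 without double-positive replicate 1, 0 without double-positive replicate 2 and 0 without double-positive replicate 3. DCX lost its call in 9 of these 12 fits and each other called gene in 10. Without double-negative replicate 2 the mitotic genes and COL1A1 named above passed. With other libraries left out the limma adjusted p reached 0.141 for ANLN and 0.146 for HMMR.

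Within the CD63-negative gate (3 libraries against 3) the genes with the smallest p for CD71 were again of neurons in part, and none passed. ZNF71 differed by -0.82 ± 0.10, the neuronal membrane protein PODXL2 by -0.90 ± 0.12, STMN4 by -1.60 ± 0.21, CYTH1 by -0.89 ± 0.13 and SYP by -0.93 ± 0.14 (limma, Benjamini-Hochberg adjusted p = 0.0570 for each). Within the CD63-positive gate the myosin MYO5B differed by -1.49 ± 0.21, DCX by -1.06 ± 0.18, the neuronal adhesion gene CNTNAP2 by 1.96 ± 0.33, TUBB3 by -0.87 ± 0.15 and the coat protein gene SEC24D by 0.83 ± 0.14 (limma, Benjamini-Hochberg adjusted p = 0.631 for each). Each of the 10 values had the same sign in 3 of 3 pairs. Limma called 0 genes in the CD63-negative gate (4298 at an unadjusted p under 0.05), where edgeR with batch on re-matched counts called 0, voom 0 and DESeq2 1897. With a looser limit of 0.10 on the limma adjusted p, 2106 genes passed in this gate and 0 in the CD63-positive gate. For CD63 among CD71-negative cells that limit gave 2122. At the threshold of 0.05 the limma count in the CD63-negative gate rose to 943 without double-negative replicate 2 and 850 without CD71-only replicate 2. In the CD63-positive gate limma called 0 (958 at an unadjusted p under 0.05), against 3 by edgeR, 0 by voom and 76 by DESeq2. With libraries left out the limma count was 2 without double-negative replicate 1, namely MYO5B and CNTNAP2.

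The interaction asks whether the CD63 difference depended on CD71. The genes with the smallest p were MYO5B at -1.96 ± 0.29, the membrane protein TMEM179 at 1.83 ± 0.35, the RNA demethylase ALKBH5 at 0.68 ± 0.13, the complement gene C4B at -1.56 ± 0.35 and the clock gene CRY1 at -0.72 ± 0.16, each with the same sign in 3 of 3 batches. A positive value means that the CD63 difference was larger or less negative in CD71-positive cells. None passed (limma, Benjamini-Hochberg adjusted p = 0.596 for each), and C4B is uncertain because C4A is nearly identical to it. Limma called 0 genes, with 1243 at an unadjusted p under 0.05. EdgeR on re-matched counts with batch called 0, voom 0 and DESeq2 21. On simulated data the test recovered 2% of changes of 1 and 61% of changes of 2 on the log2 scale, so an interaction of the smaller size was mostly not detectable with 3 libraries per population. Simulated genes varied independently, so the 61% can overstate detection of the larger size. The 0 calls therefore do not show that interactions are absent. Camera called 5 lists higher and 10 lower relative to other genes. Fry, which tests the list's own interaction, called 0 (adjusted p at least 0.709), as did camera with an estimated correlation (at least 0.813).

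Double-positive cells set against double-negative ones (3 libraries against 3) gave more called genes by limma than any other pair. SCGN differed by -6.80 ± 0.77 on the log2 scale, CALB2 by -5.68 ± 0.62, KLHL35 by -5.51 ± 0.94, STMN2 by -5.29 ± 0.61 and ACTL6B by -5.04 ± 0.48. MYOF was higher by 4.14 ± 0.35, the collagen COL3A1 by 4.11 ± 1.20, ITGB4 by 3.87 ± 0.71, NID1 by 3.86 ± 0.51 and CD74 by 3.78 ± 0.78. Each had the same sign in 3 of 3 pairs, with adjusted p from 0.00101 for MYOF to 0.0378 for COL3A1 (limma, Benjamini-Hochberg). The adjusted p of CD74 was 0.0530 without double-positive replicate 3, and that of COL3A1 was 0.133 without double-negative replicate 2, 0.106 without double-negative replicate 3, 0.0536 without CD71-only replicate 3, 0.111 without double-positive replicate 1, 0.120 without double-positive replicate 2 and 0.0575 without double-positive replicate 3. Named after their values were seen, DCX and GAD1 differed by -2.88 ± 0.18 and -3.13 ± 0.28, and COL1A1, EMP1 and HMMR by 4.97 ± 0.68, 4.13 ± 0.43 and 2.47 ± 0.38. In double-negative libraries COL1A1 and EMP1 lay below the filter level, at log2 means of -0.40 and -1.09, so the size of their differences is uncertain. In the neuron list, 1 of 19 tested members were higher, 15 lower and 3 did not pass (1 higher and 15 lower when adjusted over the list alone). The neuron list had a median log2 difference of -2.36, camera adjusted p = 1.78e-09 and adjusted p = 0.139 with an estimated correlation. In the mitosis list, 32 of 33 tested members were higher, 0 lower and 1 did not pass (32 higher and 0 lower when adjusted over the list alone). The mitosis list had a median log2 difference of 2.08, camera adjusted p = 1.78e-13 and adjusted p = 0.417 with an estimated correlation. Among matrix genes, 24 of 29 tested members were higher, 0 lower and 5 did not pass (25 higher and 0 lower when adjusted over the list alone). The matrix list had a median log2 difference of 1.82, camera adjusted p = 3.94e-10 and adjusted p = 0.131 with an estimated correlation. For the GBM states, mesenchymal-like 1 had 34 higher and 0 lower of 44, astrocyte-like 21 higher and 0 lower of 38, and NPC-like 2 0 higher and 35 lower of 48 (36 higher, 27 higher and 36 lower when adjusted over the list alone). Their camera adjusted p were 1.76e-13, 1.55e-08 and 1.28e-22, and adjusted p = 0.124, 0.398 and 0.124 with an estimated correlation.

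In this comparison 3661 genes passed, 2334 higher and 1327 lower in double-positive cells (limma with batch). EdgeR with batch on re-matched counts called 3566, edgeR without batch 411 and limma on the 6 libraries alone 864. The limma count was 1758 without double-negative replicate 1, 2277 without double-negative replicate 3 and 1657 without double-positive replicate 3.

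The 2 populations positive for a single marker were compared directly, CD71-only minus CD63-only. The genes with the smallest p were SPARC at -1.51 ± 0.20, the plasminogen activator PLAT at -1.30 ± 0.16, the collagen hydroxylase PLOD1 at -1.20 ± 0.15, PBXIP1 at -1.01 ± 0.13 and CTSB at -0.91 ± 0.11, each with the same sign in 3 of 3 pairs. None passed (limma, Benjamini-Hochberg adjusted p from 0.0843 for CTSB to 0.0849 for SPARC). Limma called 0 genes, with 3162 at an unadjusted p under 0.05. EdgeR with batch on re-matched counts called 0, voom 0 and DESeq2 598. With a library left out the limma count was 1 without double-positive replicate 1, namely PLAT.

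Of the lists followed across the 4 populations, some had their extremes in double-negative and double-positive cells and others did not. The neuron list averaged 1.13 ± 0.34 (centred log2, SD, n = 3) in double-negative, -0.29 ± 0.058 in CD63-only, 0.15 ± 0.23 in CD71-only and -0.99 ± 0.60 in double-positive libraries. The GBM mesenchymal-like state 1 list averaged -0.81 ± 0.16, 0.38 ± 0.075, -0.35 ± 0.26 and 0.78 ± 0.036 in the same order. The mitosis list averaged -1.25 ± 0.71, 0.15 ± 0.47, 0.35 ± 0.40 and 0.76 ± 0.43. The astrocyte identity list was highest in CD63-only libraries, at -0.76 ± 0.45, 0.55 ± 0.17, -0.20 ± 0.44 and 0.41 ± 0.21, and the lysosome list lowest in CD71-only ones, at -0.11 ± 0.065, 0.24 ± 0.10, -0.30 ± 0.035 and 0.18 ± 0.10.

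Some lists of other cell types had higher means in double-positive libraries as well. In double-negative, CD63-only, CD71-only and double-positive libraries the mesenchymal and mural list averaged -0.83 ± 0.29, -0.18 ± 0.54, -0.32 ± 0.13 and 1.32 ± 0.69 (centred log2, SD, n = 3), the epithelial list -0.87 ± 1.06, -0.86 ± 0.96, 0.37 ± 0.27 and 1.36 ± 1.69, the endothelial list -0.38 ± 0.60, -0.43 ± 0.36, 0.070 ± 0.32 and 0.74 ± 1.02 and the neural crest and Schwann list -0.66 ± 0.56, -0.13 ± 0.33, -0.021 ± 0.22 and 0.81 ± 1.09. Between double-positive and double-negative cells 6 of 13, 1 of 6, 1 of 5 and 2 of 9 tested members of these lists were higher and 0 lower (6, 1, 1 and 4 higher when adjusted over the list alone). Camera gave adjusted p = 0.000318, 0.0495, 0.479 and 0.0173, and adjusted p = 0.148, 0.527, 0.732 and 0.418 with an estimated correlation. The oligodendrocyte lineage list was nearly level, at -0.024 ± 0.20, 0.056 ± 0.12, -0.00076 ± 0.10 and -0.032 ± 0.25, with 3 higher and 2 lower of 11 (4 and 3 when adjusted over the list alone, camera adjusted p = 0.919, and 0.941 with an estimated correlation).

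The joint test of any difference among the 4 populations called 2229 genes (limma, Benjamini-Hochberg adjusted p under 0.05), against 1463 by edgeR with batch on re-matched counts and 8 without it. The joint count was 483 without double-negative replicate 1, 1309 without double-negative replicate 2 and 560 without double-negative replicate 3. It was 1372 without CD63-only replicate 1 and 780 without CD63-only replicate 3. It was 1319 without CD71-only replicate 1 and 963 without CD71-only replicate 3. It was 933 without double-positive replicate 1, 632 without double-positive replicate 2 and 452 without double-positive replicate 3.

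**Figure D3:**
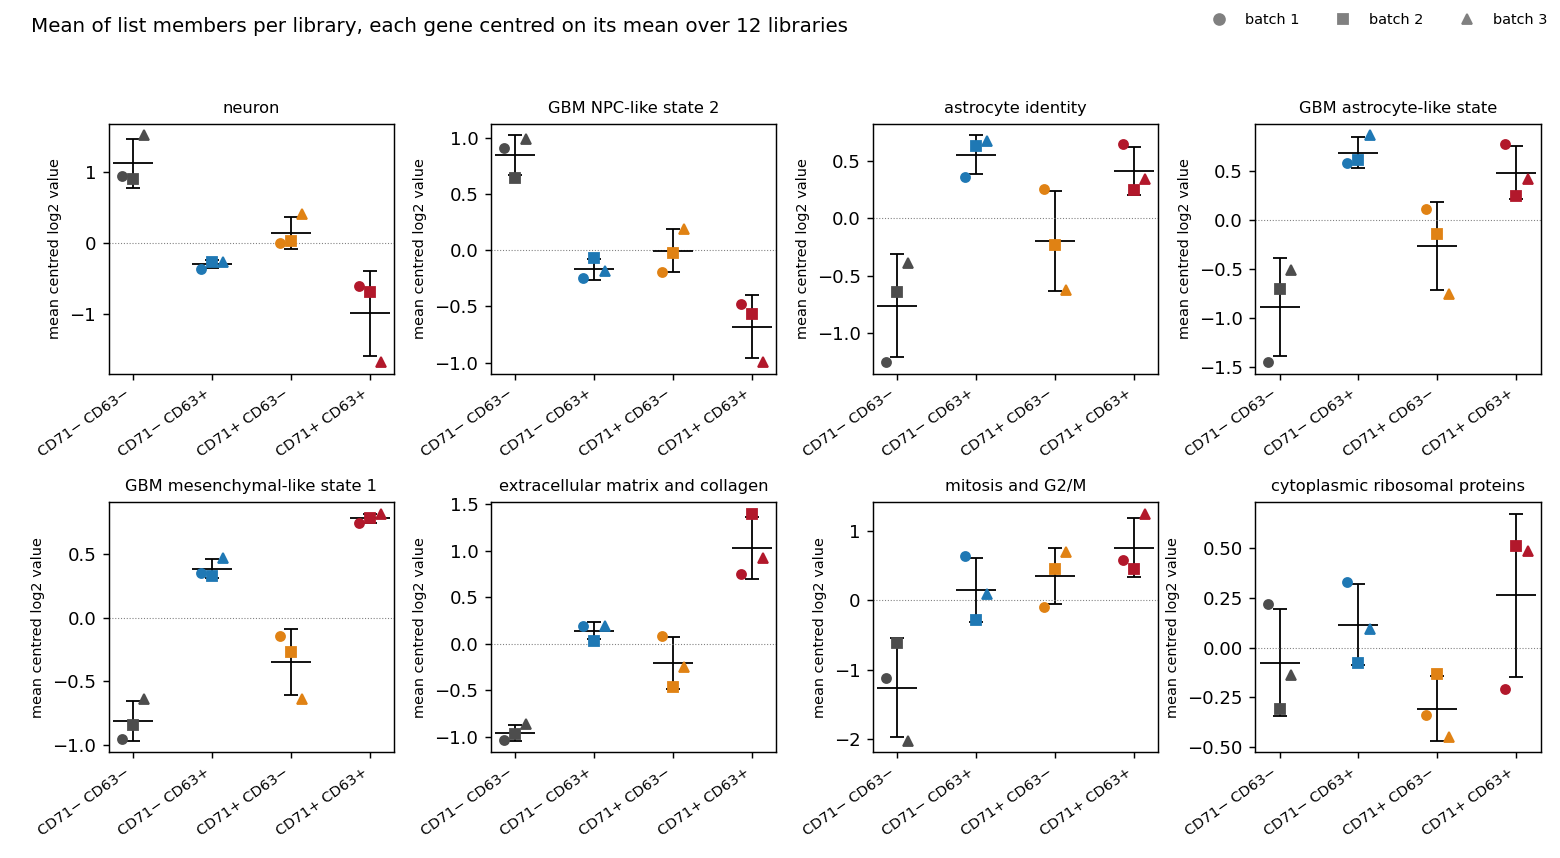
Mean over the tested members of 8 gene lists (vertical axes, log2 values with each gene centred on its mean over the 12 libraries) by population (horizontal axes). Points are libraries with 1 symbol per batch, and bars are the mean and SD of 3 libraries. The neuron list runs from 1.13 in double-negative to -0.99 in double-positive libraries, and the matrix list from -0.96 to 1.02.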

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

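The tests of the lists were not chosen after the result was seen, but the fit they rest on was. For 15 of 49 lists camera with its preset correlation called the interaction of CD71 and CD63 different from that of other genes. This does not show that the list's own CD63 difference depends on CD71, since fry, which tests that, called 0 of 49 (adjusted p at least 0.709), as did camera with an estimated correlation (at least 0.813). The median log2 interaction over the members was negative for mitosis (-0.996), astrocyte identity (-0.74), mitochondrially encoded transcripts (-0.71), the glioblastoma (GBM) astrocyte-like state (-0.65), regional HOX genes (-0.60), radial glia (-0.52), astrocyte-secreted synapse regulators (-0.51), the GBM state like oligodendrocyte precursors (-0.27), cholesterol biosynthesis (-0.23) and p53 targets (-0.19). It was positive for cytoplasmic ribosomal proteins (0.40), GBM NPC-like state 2 (0.32), housekeeping genes (0.32), glycolysis and hypoxia (0.28) and the mitochondrial respiratory chain (0.27). Limma called 0 single genes for the interaction, with 1243 at an unadjusted p under 0.05, edgeR and voom on re-matched counts with batch 0 and DESeq2 21.

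The mitosis list had the most negative median of these. Its mean over members was -1.25 ± 0.71 (centred log2, SD, n = 3) in double-negative libraries and 0.15 ± 0.47, 0.35 ± 0.40 and 0.76 ± 0.43 in CD63-only, CD71-only and double-positive ones, so in these means the step from either single marker to both was smaller than the step from none to either. No group has more than 3 libraries, so no library was tested for standing apart from its group, and no technical or biological explanation was tested for these lists.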

How the results depend on the processing

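Every alternative on re-matched counts, and the filters on the log2 values, were chosen after seeing the data, as was the reported fit itself. The others had been listed at the start. Where a count or direction changed, the cause was not tested, except that the headers of the count table assign other libraries to the populations, that fewer genes pass a fold-change limit by construction, and that leaving the batch term out of the log2 fit counts residual degrees of freedom that the removal of batch means had used.

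Under the headers of the count table, edgeR called 0 genes in each of the 10 comparisons with and without batch, with RLE (DESeq2-type) factors, with library sizes only, with a stricter filter and with none, as did limma voom (at an unadjusted p under 0.05, between 56 and 2084 genes). DESeq2 there called 0 for any difference, 1 for CD63, 11 for CD63 in CD71-negative cells, 0 for CD63 in CD71-positive cells, 1 for CD71, 2 for CD71 in CD63-positive cells, 5 for CD71-only against CD63-only and 1 for double-positive against double-negative. Camera on these counts called 13 lists for CD63, 14 lists for CD71, 7 lists for double-positive against double-negative and 24 lists for the interaction. Among lists also called in the reported fit, 4 had the same direction and 6 the opposite one for CD63. These numbers were 8 and 0 for CD71, 3 and 1 for double-positive against double-negative and 1 and 6 for the interaction.

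Of 126 values of named genes, edgeR without batch under these headers reversed 67, and 38 others lost their call. The log2 values with the sign reversed were, for CD63, ACSBG1 -0.90, ACTA2 -1.04, APOE -1.78, CALB2 3.60, CD63 -0.19, CLU -0.26, CTSB -0.17, DCX 0.65, DLX5 2.56, DLX6-AS1 2.18, EMP1 -1.36, FABP7 -0.73, FBN1 -0.55, FOXJ1 -0.85, GAD1 1.65, GSN -1.09, ITGA3 -0.52, ITGAV -0.46, ITGB3 -1.41, ITGB4 -1.22, LAMA4 -1.27, MALAT1 0.52, MYOF -1.10, NEFL -1.28, NES -0.62, NFIB 0.087, NPC2 -0.38, PMP22 -0.53, RPE65 -1.07, SCGN 3.23, SPARC -0.81, SPP1 -0.91, STEAP3 -0.27, TAGLN -0.49, TUBB3 0.071 and VIM -0.53. For CD63 in CD71-negative cells they were ACTL6B 0.25, ADORA2B -1.47, CALB2 5.16, LAMA4 -1.63, MIR4435-2HG -1.53, RGS6 -0.89, RPE65 -1.58 and SCGN 4.71. For the interaction they were ALKBH5 -0.026, CD63 -0.069, TFRC 1.10 and TMEM179 -0.036. For CD71 they were ANLN -0.0036, CD63 0.063, COL1A1 -1.44 and ITGAV 0.10. For double-positive against double-negative they were CALB2 1.12, CD74 -0.19, COL1A1 -2.75, COL3A1 -2.34, EMP1 -1.81, GAD1 0.64, ITGB4 -0.24, NID1 -0.39 and SCGN 0.33. For CD71 in CD63-negative cells it was CYTH1 0.028. For CD63 in CD71-positive cells it was MYT1 0.55. For CD71-only against CD63-only they were PBXIP1 0.0025, PLAT 2.78, PLOD1 0.28 and SPARC 1.04.

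The sort markers were fitted with 7 more settings under these headers, in the order edgeR with batch, edgeR with RLE factors, edgeR with library sizes only, edgeR without a filter, edgeR with the stricter filter, DESeq2 and limma voom, and some of their values reversed. The other named genes were not run with these settings under these headers, and were run with the matching settings on the re-matched counts or the log2 values instead. CD63 RNA for CD63 was -0.19, -0.22, -0.19, -0.26, -0.19, -0.23 and -0.16 in that order. ITGAV RNA for CD63 was -0.45, -0.49, -0.46, -0.53, -0.46, -0.50 and -0.44 in that order. TFRC RNA for CD63 was -0.027 (edgeR with batch), -0.0036 (edgeR with RLE factors), -0.038 (edgeR without a filter), -0.0094 (DESeq2) and -0.021 (limma voom). CD63 RNA for CD71 was 0.061, 0.071, 0.069, 0.085, 0.063, 0.072 and 0.0096 in that order. ITGAV RNA for CD71 was 0.15, 0.11, 0.10, 0.12, 0.10, 0.11 and 0.081 in that order. CD63 RNA for the interaction was -0.070 (edgeR with batch), -0.074 (edgeR with RLE factors), -0.065 (edgeR with library sizes only), -0.051 (edgeR without a filter), -0.064 (edgeR with the stricter filter) and -0.077 (DESeq2). ITGAV RNA for the interaction was -0.059 (edgeR with batch) and -0.14 (limma voom). TFRC RNA for the interaction was 1.18, 1.10, 1.09, 1.12, 1.10, 1.09 and 1.14 in that order.

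On re-matched counts, with batch unless stated, the counts of genes that moved by more than 1.5 times were as follows. EdgeR with batch called 1463 for any difference, 401 for CD63 in CD71-negative cells, 36 for CD63 in CD71-positive cells, 16 for CD71 and 3 for CD71 in CD63-positive cells. EdgeR with RLE factors called 417 for CD63 in CD71-negative cells, 36 for CD63 in CD71-positive cells, 19 for CD71 and 3 for CD71 in CD63-positive cells. EdgeR with library sizes only called 1233 for any difference, 337 for CD63 in CD71-negative cells, 35 for CD63 in CD71-positive cells and 3 for CD71 in CD63-positive cells. EdgeR without batch called 8 for any difference, 147 for CD63, 0 for CD63 in CD71-negative cells, 0 for CD63 in CD71-positive cells, 0 for CD71 and 411 for double-positive against double-negative. DESeq2 called 4436 for any difference, 2029 for CD63 in CD71-negative cells, 1669 for CD63 in CD71-positive cells, 1835 for CD71, 1897 for CD71 in CD63-negative cells, 76 for CD71 in CD63-positive cells, 598 for CD71-only against CD63-only and 21 for the interaction. Limma voom called 194 for CD71. Limma after thinning to the smallest total called 217 for CD63 in CD71-positive cells and 0 for CD71. The value of CD63 for the interaction lay near 0 and reversed to -0.046 (edgeR with batch), -0.036 (edgeR with RLE factors), -0.19 (edgeR with library sizes only), -0.060 (edgeR without batch), -0.016 (DESeq2), -0.032 (limma voom) and -0.053 (limma after thinning to the smallest total). The value of ITGAV for CD71 lay near 0 and reversed to 0.046 (edgeR with library sizes only), 0.021 (edgeR without batch) and 0.00064 (limma voom). For CD63, edgeR with batch shared 1287 of the 2154 genes called higher and 890 of the 920 called lower. The median CD63 difference over all genes tested was 0.075 in the reported fit. It was -0.013 by edgeR with TMM factors, -0.073 by edgeR with library sizes only and -0.080 by DESeq2. These fits also differ in tool and in the genes tested. The balance of higher and lower genes is thus relative to tool, filter and scaling together.

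On the log2 values, leaving out batch gave 5992 for any difference, 5294 for CD63, 2745 for CD63 in CD71-negative cells, 3106 for CD63 in CD71-positive cells, 2585 for CD71, 3053 for CD71 in CD63-negative cells, 1496 for CD71-only against CD63-only and 5605 for double-positive against double-negative. Without a filter limma called 1092 for any difference, 1835 for CD63, 327 for CD63 in CD71-negative cells, 88 for CD63 in CD71-positive cells and 5 for CD71, and with the stricter filter 70 for CD71. A limit of 1 on the log2 difference left 1324 for any difference, 927 for CD63, 529 for CD63 in CD71-negative cells, 271 for CD63 in CD71-positive cells, 5 for CD71 and 2006 for double-positive against double-negative. Fitted on the 6 libraries of each pair alone, limma called 0 for CD63 in CD71-negative cells, 199 for CD63 in CD71-positive cells, 1 for CD71 in CD63-negative cells and 864 for double-positive against double-negative. Of the lists called by camera, 0 for CD63, 0 for CD71, 0 for double-positive against double-negative and 0 for the interaction passed with an estimated correlation, and fry called 10 for CD71 and 0 for the interaction.

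Leaving out each of the 12 libraries in turn leaves 2 libraries in 1 population, which limma takes to vary like the others. The counts then ranged from 452 to 2341 for any difference, 1389 to 2819 for CD63, 0 to 763 for CD63 in CD71-negative cells, 0 to 640 for CD63 in CD71-positive cells, 0 to 866 for CD71, 0 to 943 for CD71 in CD63-negative cells, 0 to 2 for CD71 in CD63-positive cells, 0 to 1 for CD71-only against CD63-only and 1657 to 3809 for double-positive against double-negative, with 0 for the interaction in every case. The lists called ranged from 34 to 38 for CD63, 20 to 29 for CD71, 26 to 37 for double-positive against double-negative and 11 to 21 for the interaction. Near 0, CD63 for the interaction ranged from -0.19 to 0.18, ITGAV for CD71 ranged from -0.063 to 0.082 and TFRC for the interaction ranged from -0.34 to 0.22, while no other named gene reversed. On simulated data of this size 15% of changes of 1 and 92% of changes of 2 on the log2 scale were recovered for CD63 in CD71-positive cells and 20% of changes of 1 and 95% of changes of 2 on the log2 scale for the single positives, so differences of 1 are mostly missed in the pairs. The mouse build in the processing notes was not used.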

Other observations

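The tests of the column order and of exchanged libraries, of depth and of a share of neuron-like cells behind the CD63 differences, and of CD63-high cells among CD71-positive ones were chosen only after the result was seen. Neither of 2 further lists passed with an estimated correlation. Among genes of choroid plexus and ependyma, for CD63, there were 4 higher and 0 lower of 11 (4 and 0 adjusted over the list alone), median 0.57, camera adjusted p = 0.0674, and adjusted p = 0.454 with an estimated correlation, and FOXJ1, the master regulator of motile cilia, was higher by 1.21 ± 0.22 (adjusted p = 0.00890). Neural crest and Schwann genes had, for CD63, 4 higher and 0 lower of 9 (4 and 0 adjusted over the list alone), median 0.66, camera adjusted p = 0.0572, and adjusted p = 0.454 with an estimated correlation, and the myelin protein gene PMP22 was higher by 1.73 ± 0.22 (adjusted p = 0.00323). Of nuclear long noncoding RNAs, MIAT differed with CD63 by -0.85 ± 0.20 in 5 of 6 pairs (adjusted p = 0.0218, and 0.0551 without CD63-only replicate 1, 0.0514 without CD63-only replicate 3, 0.0623 without CD71-only replicate 3 and 0.0511 without double-positive replicate 2). MALAT1 differed by -0.62 ± 0.17 in 6 of 6 pairs (adjusted p = 0.0380). Its adjusted p was 0.0615 without double-negative replicate 1, 0.0754 without double-negative replicate 2, 0.0805 without double-negative replicate 3, 0.0899 without CD63-only replicate 1 and 0.0700 without CD63-only replicate 2. It was 0.0527 without CD71-only replicate 1, 0.0727 without CD71-only replicate 2, 0.0971 without CD71-only replicate 3, 0.0832 without double-positive replicate 2 and 0.0733 without double-positive replicate 3. None of the 14 microglia and macrophage genes passed the expression filter.

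The deposited comparison table gives each log2 difference as the second-named population minus the first, judged from the log2 table, so its sign runs against the order of the names. Its adjusted p-values lie under 0.05 for 3928 genes between double-positive and double-negative cells (2793 higher in double-positive), 1196 between CD63-only and double-negative (782 higher in CD63-only), 571 between CD71-only and double-negative (361 higher in CD71-only), 1106 between double-positive and CD71-only (776 higher in double-positive), 577 between double-positive and CD63-only (528 higher in double-positive) and 203 between CD71-only and CD63-only (105 higher in CD71-only). The p-values could be recomputed within 0.000146 by an edgeR exact test on the re-matched counts with dispersions from population and batch.

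The count table and the log2 table name the same library in only 1 of 12 columns. If the count columns stand in the text-sorted order of the sample numbers, the log2 values can be computed from them, and 100% were. If instead the headers of the log2 table were the misplaced ones, deviations of the same batch should correlate under the count headers, but the lowest correlation there was -0.43, against 0.42 in the other order. An exchange across the CD63 gate made before both tables were written would put libraries out of place in both gates, but for CD63 RNA the lowest CD63-positive library lay 0.47 above the highest negative one on the log2 scale (largest SD within a population 0.28). A sort of sample numbers as text may thus have displaced the headers of the counts, while an earlier exchange across the CD71 gate stays open, since for TFRC this difference was -0.36 (SD 0.42), although TFRC was higher with CD71 in 6 of 6 pairs.

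In CD63-positive populations 13 of 19 neuron list members were lower (1 higher), while 12 of 27, 9 of 20, 19 of 29 and 5 of 13 astrocyte, radial glia, matrix, and mesenchymal and mural members were higher (1, 0, 0 and 0 lower), by limma, and 0 of 49 lists passed with an estimated correlation (smallest adjusted p = 0.149) against 34 by camera with its preset correlation and 36 by fry. A difference in depth does not account for this. After every library was thinned to the smallest total, 2668 genes passed for CD63. They included 1669 of the 2154 genes called higher in the reported fit and 810 of the 920 called lower. Camera with its preset correlation then called 37 lists, with all 34 of the reported ones in the same direction. A larger share of neuron-like cells among CD63-negative ones, with nothing else different, would raise glial genes by 1 common amount if neurons expressed none of them. Of the 47 astrocyte and radial glia genes, 42.6% had a 95% interval that left out their common median of 0.86, 10 above it and 10 below, but how much of each gene neurons express is not measured, so this does not exclude such a share. It therefore stays open, with no gate for neurons stated beyond CD51, as does a difference in cell state between the sorted populations as an untested biological explanation.

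Genes tended to move the same way with CD71 as with CD63: of the genes called for CD63, 75.6% of those higher and 86.0% of those lower had the same sign with CD71, and the correlation across the 16030 genes, which are not independent, was 0.52. Chance was not excluded, since 6 of 64 sign patterns of the CD71 differences gave a correlation as far from 0, the highest at 0.60. Depth does not account for it, as the correlation was 0.51 after thinning. By the slope of the CD71 differences on the CD63 differences (0.40), CD63-high cells in the CD71-positive gates would have raised CD63 RNA by 0.36. CD63 RNA differed by -0.16 with an upper 95% bound of 0.084. The 0.36 carries no error and assumes that such cells bring CD63 RNA in proportion, while sorting was on surface protein. Such cells are therefore not excluded. A biological link between the markers stays open and was not tested.

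Other splits of the samples into groups of the same sizes, made within batches, were fitted for the comparisons that use all 12 libraries, 100 splits each. For CD63, with 3074 genes, 1 split was as large, the real one, and the highest other had 156. For any difference, with 2229, 1 split was as large, with a highest other of 726. Chance can thus be excluded for both at a share of 0.05, under the headers of the log2 table. Their share of 0.01 is the lowest that 100 splits can give. In the other splits the CD63 difference enters the spread within groups, so the gap in counts adds little to the rank. For CD71, with 10, chance is not excluded at the share of 0.05 set at the start. All in all 5 of 100 splits were as large, the real one included. The highest other, at 1266, parts all 12 libraries as CD63 does and so shows the CD63 structure of the samples. Leaving it out, which was not planned, gives 4 of 99, a share under 0.05, with a highest other of 1247. That split and 1 with 1055 genes part 10 of the 12 as CD63 does, and 1 with 272 genes parts 8. The splits as large thus carry CD63 structure in part, so they do not measure chance for CD71 alone. For the interaction the real count of 0 makes every split as large (100 of 100, highest other 3059), so the splits say nothing about chance. Its highest split is likewise that of CD63. For the pairs of populations the 10 splits of 6 libraries are too few for a share under 0.05. The real value and the highest other were 833 and 51 for CD63 in CD71-negative cells, 634 and 0 in CD71-positive cells, 3661 and 0 for double-positive against double-negative, 0 and 0 for CD71 in either CD63 gate, and 0 and 261 for CD71-only against CD63-only.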
